A study of Mus musculus with 16 samples.

How the data were processed

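Total RNA from snap-frozen mammary tumours and from normal mammary glands of mice was labelled as biotin cRNA and measured on Affymetrix Mouse Genome 430A 2.0 arrays. The 16 arrays were grouped as the labels give them: 3 of normal gland, 7 of tumours with the STAT5ca transgene and 6 of tumours with the STAT5Δ750 transgene. No date, batch or shared replicate number is given in the labels, so no batch could be tested and no arrays were paired.

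The deposited values were the authors' MAS5 signals, in units of intensity on a linear scale, 1 per probe set and array, for 22690 probe sets. The submitters' processing notes name MAS5 without a version. The mean signal after removal of the lowest and highest 2 percent of probe sets was 249.97 or 249.96 on each of the 16 arrays, so that each array had been scaled to about the same trimmed mean. Array medians ran from 57.3 to 90.7, a ratio of 1.58, above the limit of 1.5 set before the data were examined, and each array was therefore scaled to a common median of 75.9. The scaled signals were used as log2 of the signal plus 7.9, the 20th percentile of all deposited values. The number of arrays limits the precision, and signals near this offset carry little information on change.

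A probe set was kept if its signal was above 35.4, the 40th percentile of all deposited values, on at least 3 arrays, which left 15764 probe sets. Of all probe sets, 20393 carried 1 gene symbol, 691 carried several, and 1606, among them 64 controls, were unnamed here. Symbols were checked by gene identifier against the annotation of mouse genome build GRCm38.p6, used for names only, and 0 were changed. For each gene, the probe set with the highest mean log2 value over the 16 arrays was used, which gave 9260 genes.

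The groups were compared with limma 3.58.1 in R 4.3.3, in 1 model with 3 groups that share an estimate of the spread per gene, with 13 residual and 2.98 prior degrees of freedom. P values were two-sided and adjusted by the Benjamini-Hochberg method within each comparison, with a threshold of 0.05. The 3 comparisons were STAT5ca tumours against gland, STAT5Δ750 tumours against gland, and STAT5ca against STAT5Δ750 tumours. Errors of log2 changes are the standard errors of the model.

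The 29 gene lists, written before any value was seen, were milk proteins and secretory differentiation, STAT5 targets and prolactin signalling, luminal epithelium, hormone sensing epithelium, basal and myoepithelial cells, squamous and cornified epithelium, mesenchymal transition, fibroblasts and collagen matrix, adipocytes, skeletal muscle, T and NK cells, B and plasma cells, macrophages, granulocytes and mast cells, endothelium, mitosis and proliferation, DNA replication, fatty acid and triglyceride synthesis, cholesterol synthesis, interferon response, MHC class II presentation, matrix proteases and inhibitors, Wnt targets and antagonists, glycolysis and hypoxia, oxidative phosphorylation, unfolded protein response, apoptosis regulators, immediate early genes and ribosomal proteins. Each was tested with camera at its preset correlation of 0.01, with adjustment over the 87 tests of all lists and comparisons. Camera with an estimated correlation and fry were run beside it. Genes were named by a rule set with the lists. It takes, per comparison, the 10 largest rises and the 10 largest falls among passing genes, and up to 4 members of each described list with the smallest adjusted p. It also takes Stat5a, Stat5b, Stat3, Csn2, Wap, Krt8, Krt14, Cish and Mki67. Only genes with a probe set that carries 1 symbol are named.

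The alternatives planned were quantile normalization, centring of each array on its median log2 value, an offset of 1 or of the 40th percentile, a floor at the 20th percentile, no filter, a filter at the 60th percentile (134.8), all probe sets, the mean of a gene's probe sets, limma with trend and robust, array quality weights, only the arrays of the 2 groups compared, the Gapdh 3'/5' ratio as a covariate, a fold change of at least 2, a Welch test per gene and leaving out each of the 16 arrays in turn. Alternatives added after the data were seen were the deposited scaling, the beta-actin 3'/5' ratio as a covariate, the deposited scaling without STAT5ca_177, and leaving out STAT5ca_124 and STAT5Δ750_254 together.

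The procedure was tested on simulated data, in 5 draws of 200 changed genes. Genes changed 2-fold were recovered in 26.4%, 19.0% and 38.8% of cases in the 3 comparisons, and genes changed 4-fold in 67.2%, 66.4% and 78.8%, with 6.59%, 5.53% and 5.31% false calls. Of 29 shifted lists 26 were called, and 4 of 812 lists without a shift. The simulated genes were drawn independently of one another, so these list counts do not hold for genes that move together. The estimated correlation of the muscle list was 0.878. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.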

Results

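Gene expression was measured on 16 arrays, each holding RNA from mice of the FVB/N background. 3 arrays held normal mammary gland. 7 held mammary tumours from mice with the STAT5ca transgene, which encodes a constitutively active form of STAT5, the transcription factor that carries prolactin signals in mammary epithelium. 6 held mammary tumours from mice with the STAT5Δ750 transgene, which encodes STAT5 without part of its C-terminus. The labels do not give the stage of the glands, such as virgin or lactating, the age of the mice or the histology of the tumours. Each array gave 1 signal for each of 22690 probe sets, with medians between 57.3 and 90.7, and 9260 genes were tested. The number of arrays, 3, 7 and 6, limits the precision.

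The glands resembled one another more than the tumours did. The mean correlation of an array with the others of its group was 0.960 ± 0.007 (SD, n = 3) for gland, 0.816 ± 0.068 (SD, n = 7) for STAT5ca tumours and 0.865 ± 0.013 (SD, n = 6) for STAT5Δ750 tumours. The array of tumour STAT5ca_177 had a mean correlation of 0.668 with its group, against 0.808 to 0.861 for the other STAT5ca arrays. Arrays are named as in the labels. The deposited signal of STAT5ca_177 for Krt8, a keratin of luminal epithelium, was 25.3, against 3836 to 5376 on the other STAT5ca arrays and 708 to 1880 on the glands. The ratio of the 3' to the 5' beta-actin control probe sets, which rises as RNA degrades, was 1.16 ± 0.09 (SD, n = 3) in gland, 3.23 ± 1.56 (SD, n = 7) in STAT5ca tumours and 2.16 ± 0.86 (SD, n = 6) in STAT5Δ750 tumours, and every tumour array lay above every gland.

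**Figure D1:**
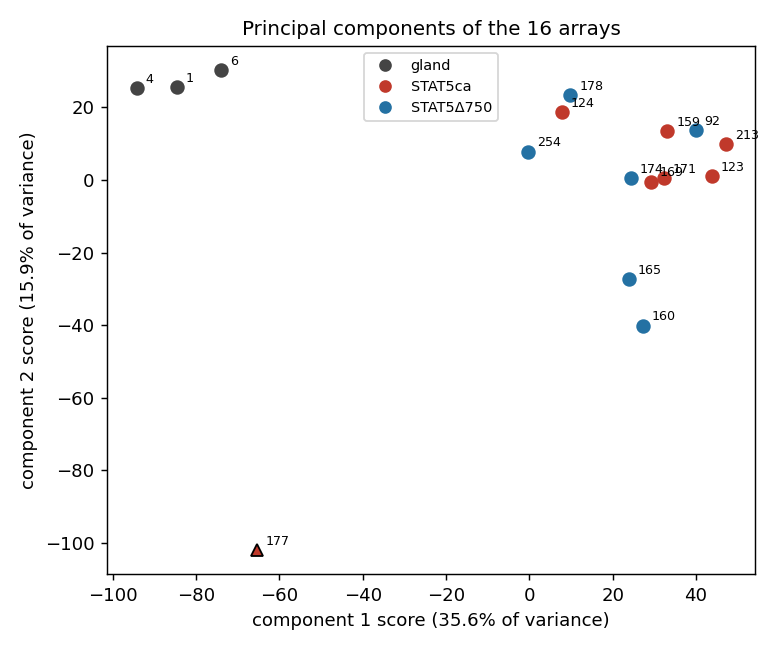
Scores of the 16 arrays on the first 2 principal components of log2 signal, which hold 35.6% and 15.9% of the variance, with 1 point per array, its number beside it and its group in colour. The 3 glands have the lowest scores on component 1, -94.2 to -73.9, followed by STAT5ca_177 (triangle) at -65.4, which has the lowest score on component 2, -102.

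The comparison of STAT5ca tumours with gland asked which genes differ between tumours that arise with active STAT5 and normal tissue. The largest falls were in genes of skeletal muscle, which lies next to the gland, and in Cd209b, a lectin of macrophages in lymphoid tissue, at -6.76 ± 1.25 (log2 change ± SE, 7 tumours against 3 glands). Actn3, Tnnt3, Myh2, Pvalb and Ttn, which encode sarcomere or calcium-binding proteins of muscle fibres, and Pygm, Ckmt2, Pgam2 and Apobec2, which encode enzymes of muscle, fell by 6.37 to 6.58 on the log2 scale. The largest rises were in Klk10 at 4.91 ± 1.57 and Klk11 at 3.77 ± 1.23, kallikrein proteases, and in Mmp13, collagenase 3, at 4.60 ± 1.32. Olfml3, a secreted matrix protein, rose by 3.68 ± 0.69, Spc25, a kinetochore protein, by 3.27 ± 0.44, and Pbk, a mitotic kinase, by 3.21 ± 0.48. Dyrk3, a kinase, rose by 3.22 ± 0.56, Arg1, arginase 1, by 3.19 ± 0.94, Trem2, a receptor of macrophages, by 3.15 ± 0.92, and Gabrp, a GABA receptor subunit, by 3.28 ± 1.02. Each of these 20 genes moved in its direction on all 7 tumour arrays, except Gabrp on 6.

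By limma, 2154 of 9260 genes passed, 1284 higher and 870 lower in STAT5ca tumours, and 3405 had an unadjusted p under 0.05. The median of all genes was shifted by 0.26 on the log2 scale, so that list medians below are relative to it unless called raw. List means are raw. Under the deposited scaling, with a median shift of -0.02, 1848 genes passed, 622 higher and 1226 lower, and under quantile normalization 2008 passed, 872 higher and 1136 lower, so that the side with more genes depends on the scaling. Leaving out gland 1, 4 or 6 gave 1179, 1190 or 1315 genes, and with the actin ratio in the model 772 genes passed. With the Gapdh ratio in its place 2249 genes passed. Without any 1 of the 3 glands, Klk10, Klk11, Mmp13, Gabrp, Arg1 and Trem2 no longer passed, with adjusted p up to 0.100, 0.134, 0.0738, 0.105, 0.107 and 0.0832. Gabrp also lost its call without STAT5ca_171, Klk10 without STAT5ca_123, STAT5ca_124, STAT5ca_213 or STAT5ca_171, and Klk11 without STAT5ca_124, STAT5ca_213, STAT5ca_159 or STAT5ca_171. With the actin ratio in the model these 6 genes and Tnnt3, Myh2, Ckmt2, Ttn and Olfml3 did not pass. Of the genes named further on, Igf1, Tnfsf11, Ccnd1, Cdh1, Foxa1, Dpt, Col1a1, Cd14, Mcpt4, Lig1, Gpam, Oas1a, Timp1, Lef1, Slc2a1, Rpl10a and Mki67 also did not pass in STAT5ca tumours with this ratio. Under the deposited scaling Klk11, Gabrp, Cd14, Bst2 and Rpl10a did not pass.

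The comparison of STAT5Δ750 tumours with gland asked the same of tumours that arise with truncated STAT5. The largest falls were in Marco, a scavenger receptor of macrophages, at -7.10 ± 1.86 (log2 change ± SE, 6 tumours against 3 glands), and in Ucp1, the uncoupling protein of brown fat, at -6.66 ± 0.89. Cd209b stood at -6.64 ± 1.28, Cox8b, a cytochrome oxidase subunit of brown fat and muscle, at -6.12 ± 1.13, and Pck1, an enzyme of glyceroneogenesis, at -6.00 ± 0.61. The muscle genes Actn3, Ryr1, Pvalb, Myh2 and Pgam2 fell by 5.79 to 6.23. The largest rises were in Mmp13 at 4.76 ± 1.35, Igfbp2, an IGF-binding protein, at 3.81 ± 1.26, Dyrk3 at 3.73 ± 0.57 and Psrc1, a protein of the mitotic spindle, at 3.52 ± 0.52. Perp, a desmosome protein, Ube2c, a ubiquitin-conjugating enzyme of mitosis, Nkd2, a Wnt antagonist, Dmkn, dermokine, Pbk and Phlda2, an imprinted gene, rose by 3.16 to 3.42. Each of these 20 genes moved in its direction on all 6 tumour arrays. On STAT5Δ750_254 Marco had a log2 signal of 8.40 and Cd209b of 9.40. On the other STAT5Δ750 tumours they had 3.05 to 3.15 and 3.14 to 3.68.

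By limma, 1823 genes passed in STAT5Δ750 tumours against gland, 860 higher and 963 lower, with a median shift of 0.08, and 3105 had an unadjusted p under 0.05. Under the deposited scaling 2005 passed, 706 higher and 1299 lower, and under quantile normalization 2173, 896 higher and 1277 lower. Leaving out gland 1, 4 or 6 gave 950, 835 or 1207 genes. With only the arrays of the 2 groups in the model 2826 genes passed, and with the deposited scaling and without STAT5ca_177 2752 passed. Igfbp2, Nkd2, Dmkn, Mmp13 and Perp no longer passed without any 1 of the 3 glands, with adjusted p up to 0.146, 0.157, 0.208, 0.0801 and 0.0905, and Marco without gland 1 or 4, with adjusted p up to 0.0637. Igfbp2 lost its call without 7 of the tumour arrays as well (STAT5ca_124, STAT5ca_213, STAT5ca_159 or STAT5ca_171, STAT5Δ750_254, STAT5Δ750_165 or STAT5Δ750_160), Nkd2 without 6 (STAT5ca_124, STAT5ca_213 or STAT5ca_159, STAT5Δ750_165, STAT5Δ750_174 or STAT5Δ750_160) and Dmkn without 7 (STAT5ca_124 or STAT5ca_159, STAT5Δ750_254, STAT5Δ750_165, STAT5Δ750_174, STAT5Δ750_178 or STAT5Δ750_160). With the actin ratio in the model Mmp13, Igfbp2, Perp, Nkd2 and Dmkn did not pass, nor did Cldn4, Krt7, Dpt, Mcpt4, H2-Eb1 and Mki67 of the genes named further on. Nkd2 and Dmkn also did not pass under the deposited scaling.

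Muscle, fat, lymphocyte and endothelial genes were lower in both tumour types. How far falls of other genes and lists named below follow a differing share of these tissues was not tested. Each passing gene named from here on moved in its direction on every array of its tumour group, except where a number of arrays is given. Of 16 skeletal muscle genes, 16 fell in STAT5ca and 15 in STAT5Δ750 tumours, and 16 and 16 adjusted over the list alone. Casq1, the calcium store protein of muscle, stood at -6.29 ± 0.70 and -5.77 ± 0.72, and Eno3, muscle enolase, at -5.20 ± 0.73 and -4.60 ± 0.75. Of 17 adipocyte genes, 15 and 16 fell, and 17 and 17 adjusted over the list alone, among them Aqp7, the glycerol channel, at -3.36 ± 0.24 and -3.20 ± 0.24, and Lep, leptin, at -4.09 ± 0.41 and -4.08 ± 0.42. The medians relative to all genes were -6.20 and -5.19 for muscle and -3.89 and -3.91 for adipocytes. By camera, adjusted p = 4.28e-14 and 1.50e-10 for muscle and 1.55e-17 and 4.08e-16 for adipocytes. These became adjusted p = 0.335 and 0.343 for muscle and 0.152 and 0.152 for adipocytes with an estimated correlation. With the actin ratio in the model the raw muscle medians went from -5.94 to -3.92 and from -5.11 to -4.13.

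Of 17 T and NK cell genes, 14 fell in STAT5ca and 15 in STAT5Δ750 tumours, and 15 and 15 adjusted over the list alone. Cd5, Cd247 and Cd28, surface and signalling proteins of T cells, stood at -3.64 ± 0.49, -3.39 ± 0.52 and -3.90 ± 0.64 in STAT5ca tumours, and Cd2, an adhesion protein of T cells, at -3.76 ± 0.66. In STAT5Δ750 tumours Cd5 stood at -3.25 ± 0.50. Of 11 B and plasma cell genes, 10 and 9 fell, and 11 and 11 adjusted over the list alone, with Ms4a1, which encodes CD20, at -4.63 ± 0.93 and -4.47 ± 0.95. Cd79a, part of the B cell receptor, stood at -4.63 ± 0.93 in STAT5ca tumours. The medians relative to all genes were -3.40 and -3.42 for T and NK cells and -3.64 and -3.68 for B cells, with camera adjusted p = 1.78e-11, 1.72e-10, 3.04e-08 and 3.49e-07. These became adjusted p = 0.335, 0.335, 0.342 and 0.343 with an estimated correlation. The mean of the B cell list was 8.59 on STAT5ca_124 and 8.35 on STAT5Δ750_254, against 4.46 to 6.20 on the other tumour arrays.

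Of 15 endothelial genes, 10 fell in each tumour type, and 10 and 10 adjusted over the list alone. Kdr, a VEGF receptor, stood at -2.30 ± 0.20 and -2.18 ± 0.20, Egfl7 at -2.49 ± 0.33 and -1.86 ± 0.34, and Pecam1, an adhesion protein of vessels, at -2.14 ± 0.31 and -1.67 ± 0.32. Camera called endothelium lower, with adjusted p = 7.10e-10 and 3.91e-07, and adjusted p = 0.166 and 0.248 with an estimated correlation. Of 9 granulocyte and mast cell genes, 4 and 3 fell, and 5 and 4 adjusted over the list alone, with Mcpt4, a mast cell protease, at -2.38 ± 0.54 and -2.10 ± 0.56. Granulocytes and mast cells had camera adjusted p = 0.00266 and 0.0353, and adjusted p = 0.444 and 0.662 with an estimated correlation. On STAT5Δ750_254 the list mean was 8.27, above the highest gland, 8.01, against 5.24 to 6.19 on the other STAT5Δ750 tumours. The second call was lost without gland 1, gland 6 or STAT5Δ750_92, with adjusted p of 0.0660 to 0.0997, under the deposited scaling, with adjusted p = 0.0836, under quantile normalization (0.0774) and with the actin ratio in the model (0.0736). Mcpt4 did not pass in STAT5Δ750 tumours without gland 1 or 4, with adjusted p up to 0.0789.

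**Figure D2:**
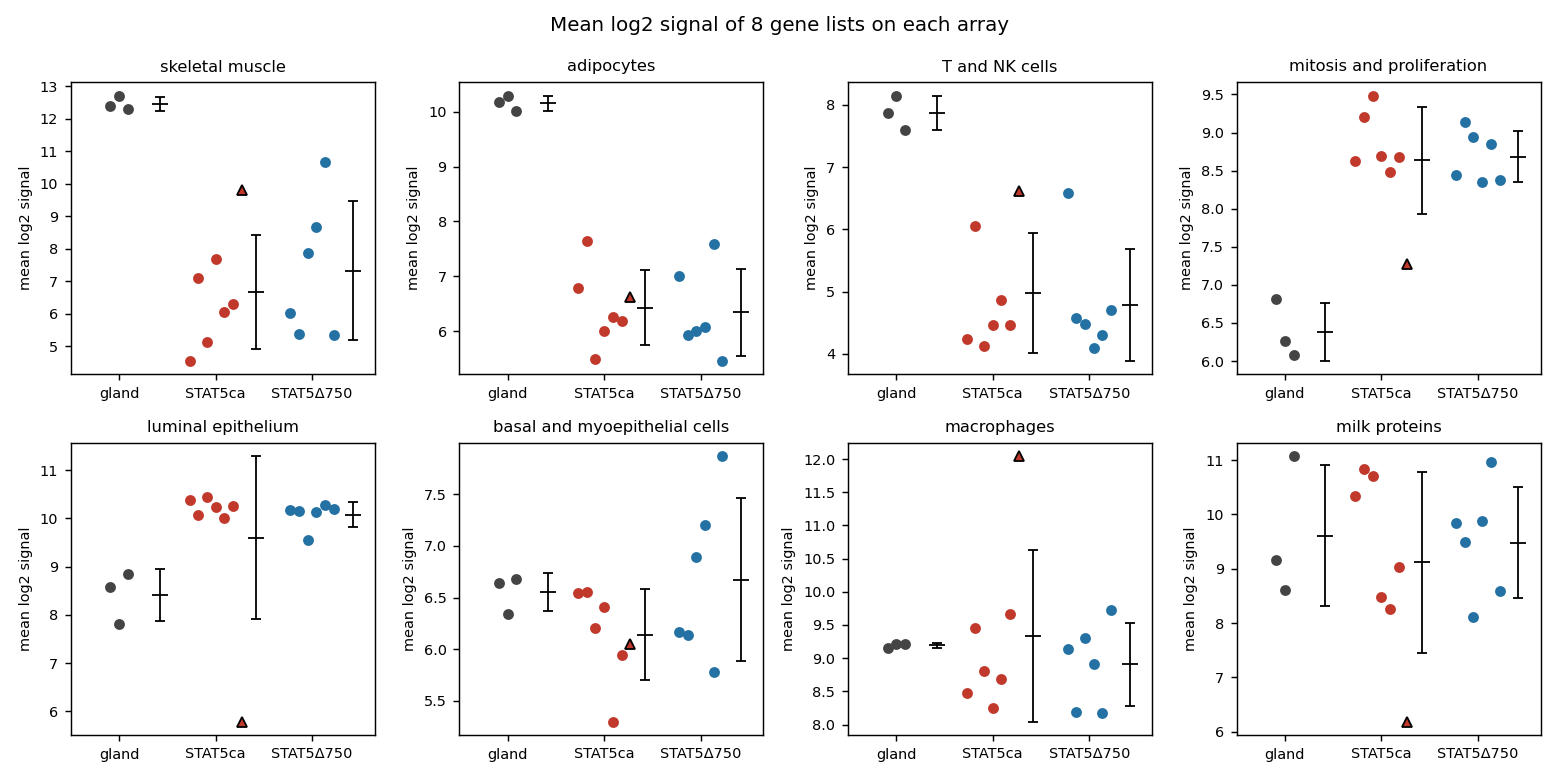
Mean log2 signal of the tested genes of 8 lists on each array, 1 point per array, with the mean and SD of each group beside its points and STAT5ca_177 as a triangle. On the muscle list the 3 glands lie between 12.30 and 12.71 and the tumours between 4.55 and 10.66, and on the luminal list STAT5ca_177 lies at 5.79.

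Genes of cell division were higher in both tumour types. Of 24 mitosis genes, 24 rose in STAT5ca and 23 in STAT5Δ750 tumours, and 24 and 24 adjusted over the list alone. Cdk1, the mitotic kinase, rose by 2.89 ± 0.37 and 3.08 ± 0.37, and Mki67, the Ki-67 antigen of dividing cells, by 1.89 ± 0.42 and 1.58 ± 0.44. Ube2c rose by 3.04 ± 0.44 and Tpx2, a spindle protein, by 2.31 ± 0.35 in STAT5ca tumours. Of 22 DNA replication genes, 20 and 19 rose, and 22 and 21 adjusted over the list alone, with the clamp loader subunits Rfc4 at 1.59 ± 0.26 and 1.66 ± 0.27 and Rfc3 at 1.77 ± 0.31 and 1.68 ± 0.32, and Lig1, a DNA ligase, at 1.91 ± 0.34 in STAT5ca tumours. The medians relative to all genes were 2.05 and 2.30 for mitosis and 1.32 and 1.39 for replication. By camera, adjusted p = 4.28e-14 and 2.36e-17 for mitosis and 2.00e-09 and 4.58e-11 for replication. These became adjusted p = 0.342 and 0.335 for mitosis and 0.343 and 0.342 for replication with an estimated correlation. Mki67 did not pass in STAT5Δ750 tumours without gland 4 or 6, with adjusted p up to 0.0848.

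Of 16 genes of cholesterol synthesis, 5 rose in STAT5ca and 4 in STAT5Δ750 tumours, and 7 and 8 adjusted over the list alone. Fdps, farnesyl diphosphate synthase, rose by 2.60 ± 0.34 and 2.75 ± 0.35, and Sqle, squalene epoxidase, by 2.13 ± 0.36 and 2.45 ± 0.37. The list had camera adjusted p = 0.00705 and 0.00204, and adjusted p = 0.662 and 0.612 with an estimated correlation. With the actin ratio in the model the first became adjusted p = 0.380, and its raw median went from 0.95 to 0.10. Of 18 genes of fatty acid and triglyceride synthesis, 2 rose and 4 fell in STAT5ca tumours and 1 rose and 4 fell in STAT5Δ750 tumours, and the counts adjusted over the list alone were 2, 4, 1 and 4. Scd2, a desaturase, rose by 1.75 ± 0.24 and 1.74 ± 0.24, while Elovl6, an elongase, stood at -2.52 ± 0.63 and -2.31 ± 0.65 and Gpam, the first enzyme of glycerolipid synthesis, at -1.61 ± 0.45 and -2.07 ± 0.46. The list was not called, with camera adjusted p = 0.165 and 0.310, except in STAT5ca tumours without gland 4, with adjusted p = 0.0493. Elovl6 lost its call in STAT5ca tumours without gland 6 (adjusted p = 0.0544) and in STAT5Δ750 tumours without gland 1 or 6 (adjusted p up to 0.0872), and Gpam in STAT5ca tumours without gland 1 or 4 (adjusted p up to 0.0799).

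Of 17 genes of glycolysis and hypoxia, 4 rose in STAT5ca tumours, and 5 rose and 1 fell in STAT5Δ750 tumours. The counts adjusted over the list alone were 4, 6 and 1. Pfkl, a phosphofructokinase, rose by 1.91 ± 0.33 and 1.56 ± 0.34, and Slc2a1, the glucose transporter GLUT1, by 1.52 ± 0.39 and 1.81 ± 0.40. For glycolysis, camera gave adjusted p = 0.236 and 0.0307, and the second became adjusted p = 0.686 with an estimated correlation and 0.0570 without STAT5Δ750_92. Of 19 genes of oxidative phosphorylation, 2 and 4 fell, and 1 and 4 adjusted over the list alone, with Ndufs1, a subunit of complex I, at -1.15 ± 0.24 and -0.99 ± 0.25. Oxidative phosphorylation had camera adjusted p = 0.0188 and 0.00516, and adjusted p = 0.751 and 0.686 with an estimated correlation, and the first became 0.0514 without STAT5ca_177. Ndufs1 did not pass in STAT5Δ750 tumours without gland 1 or 4, with adjusted p up to 0.0840. Of 16 genes of the unfolded protein response, 4 rose in each, and 6 and 5 adjusted over the list alone, with Pdia4, a disulfide isomerase, at 1.15 ± 0.20 and 1.16 ± 0.21. Unfolded protein genes had camera adjusted p = 0.0714 and 0.0267, and the second became adjusted p = 0.684 with an estimated correlation and 0.0561 without gland 4. The first became 0.0298 to 0.0406 without gland 6, STAT5ca_159 or STAT5ca_171. Of 13 ribosomal protein genes, 1 rose in STAT5ca tumours, Rpl10a at 0.56 ± 0.19, and 0 in STAT5Δ750 tumours, where 0 passed by limma and 0 adjusted over the list alone. Camera gave adjusted p = 0.0557 and 0.0418, with medians of 0.19 and 0.24 relative to all genes, and adjusted p = 0.794 and 0.764 with an estimated correlation. Rpl10a lost its call without any gland and without STAT5ca_123, STAT5ca_124 or STAT5ca_213 or STAT5Δ750_174, with adjusted p up to 0.155. The second list call was lost without gland 1 or 6, STAT5ca_177 or STAT5Δ750_254, STAT5Δ750_92 or STAT5Δ750_178 (adjusted p 0.0630 to 0.111), under the deposited scaling (0.0941) and under quantile normalization (0.0848), and the first list was called without gland 4, STAT5ca_169 or STAT5ca_171, or STAT5Δ750_160 (adjusted p 0.0272 to 0.0459).

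Luminal epithelium genes depended on 1 array. Of 18 such genes, 1 rose in STAT5ca tumours, Cdh1, E-cadherin, at 1.42 ± 0.31, and 4 rose in STAT5Δ750 tumours, and 1 and 4 adjusted over the list alone. In STAT5Δ750 tumours Cdh1 stood at 1.5 ± 0.32, Cldn4, a tight junction protein, at 2.98 ± 0.82 and the keratin Krt7 at 3.0 ± 0.91. By camera, adjusted p = 0.117 and 0.00266, and the second became adjusted p = 0.684 with an estimated correlation. Without STAT5ca_177, 14 of 18 rose in STAT5ca tumours and 13 of 18 in STAT5Δ750 tumours, and the first camera value became 6.28e-07. Without gland 6 it was 0.0328, and under the deposited scaling 0.0335. Krt8 stood at 1.16 ± 1.15 in STAT5ca tumours (limma adjusted p = 0.488), higher on 6 of 7 arrays, and at 1.94 ± 1.17 in STAT5Δ750 tumours (limma adjusted p = 0.263), higher on 6 of 6. Without STAT5ca_177 these became 2.16 ± 0.26 (adjusted p = 2.82e-05) and 1.94 ± 0.26 (adjusted p = 0.000101), since the groups share 1 estimate of the spread. Cldn4 did not pass in STAT5Δ750 tumours without gland 4 or 6 (adjusted p up to 0.0984), nor Krt7 without any gland or without STAT5Δ750_165, STAT5Δ750_174 or STAT5Δ750_160 (adjusted p up to 0.119).

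Of 7 hormone sensing epithelium genes tested, from 13 listed, 5 fell in STAT5ca and 3 in STAT5Δ750 tumours, and 5 and 4 adjusted over the list alone. Foxa1, a cofactor of the oestrogen receptor, stood at -2.81 ± 0.70 in STAT5ca tumours, and Tnfsf11, the RANK ligand, at -2.49 ± 0.47 and -2.38 ± 0.48. Hormone sensing genes had camera adjusted p = 0.000727 and 0.0172, and adjusted p = 0.248 and 0.342 with an estimated correlation. Both calls were lost with the filter at the 60th percentile. The second was also lost without a filter, and under the deposited scaling without STAT5ca_177. Of 17 basal and myoepithelial genes, 5 and 3 fell, and 5 fell in STAT5ca tumours and 3 fell and 1 rose in STAT5Δ750 tumours adjusted over the list alone. Myh11, smooth muscle myosin, stood at -3.20 ± 0.39 and -2.71 ± 0.40, and Cnn1, calponin, at -1.99 ± 0.36 in STAT5ca tumours. Krt14, a basal keratin, stood at 1.38 ± 1.36 and 1.87 ± 1.40 and did not pass. The basal list had camera adjusted p = 0.0143 and 0.454, and the first became adjusted p = 0.605 with an estimated correlation, 0.0502 under the deposited scaling, 0.0848 under quantile normalization and 0.0770 with the actin ratio in the model. In STAT5Δ750 tumours the basal list had a median of -0.34, or -0.26 raw, and a mean of 0.12. Of 10 squamous epithelium genes, 0 and 1 rose by limma, the second being Dmkn, and 0 and 0 adjusted over the list alone. They had camera adjusted p = 0.259 and 0.0453, and the second became adjusted p = 0.684 with an estimated correlation. That call was lost without gland 1 or 4, STAT5ca_169 or STAT5ca_177, or STAT5Δ750_174, STAT5Δ750_178 or STAT5Δ750_160 (adjusted p 0.0505 to 0.116).

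The probe sets of Stat5a and Stat5b were not higher in the tumours. Stat5b stood at -1.28 ± 0.35 in STAT5Δ750 tumours (limma adjusted p = 0.0184), lower on 6 of 6 arrays, and at -0.64 ± 0.34 in STAT5ca tumours (adjusted p = 0.190), lower on 6 of 7. Under quantile normalization the second Stat5b value, STAT5ca against gland, became -0.97 with adjusted p = 0.0452. Stat5a stood at -0.72 ± 0.54 and -1.22 ± 0.55 (adjusted p = 0.345 and 0.129). A second Stat5a probe set stood closer to the glands, at -0.26 ± 0.70 in STAT5ca and -0.12 ± 0.72 in STAT5Δ750 tumours. The first Stat5b value lost its call without gland 1 or 4 (adjusted p up to 0.0962), and a second Stat5b probe set stood at -0.19 ± 0.40. Whether the probes reach the transgenes was not tested. Of 19 genes of the list of STAT5 targets and prolactin signalling, 3 rose and 4 fell in STAT5ca tumours, and 2 rose and 6 fell in STAT5Δ750 tumours. The counts adjusted over the list alone were 4, 4, 3 and 7. Igf1, a growth factor, stood at -2.12 ± 0.38 and -2.09 ± 0.39, and Pim2, a kinase, at -1.61 ± 0.33 and -1.72 ± 0.34. Ccnd1, cyclin D1, rose by 2.87 ± 0.65 in STAT5ca tumours and Myc, a growth regulator, by 1.29 ± 0.34 in STAT5Δ750 tumours. Cish, a STAT5 feedback inhibitor, stood at -0.36 ± 0.51 and -0.26 ± 0.52 and did not pass. Stat3 stood at 0.51 ± 0.20 and 0.53 ± 0.20 and did not pass. Without STAT5ca_177, Stat3 passed in STAT5ca tumours (adjusted p = 0.0474). A second Stat3 probe set stood at 1.20 ± 0.51 and 1.62 ± 0.52, and over all probe sets passed in STAT5Δ750 tumours (adjusted p = 0.0401), higher on 6 of 6 arrays, and not in STAT5ca tumours (adjusted p = 0.104), higher on 6 of 7. Its call in STAT5Δ750 tumours was lost without gland 1 or 4 or STAT5Δ750_254, STAT5Δ750_92, STAT5Δ750_165, STAT5Δ750_178 or STAT5Δ750_160 (adjusted p up to 0.248), while its value in STAT5ca tumours passed without STAT5ca_124 (adjusted p = 0.0418). The target list had camera adjusted p = 0.0420 and 0.153, and the first became adjusted p = 0.342 with an estimated correlation, 0.0958 under the deposited scaling, 0.0623 under quantile normalization and 0.109 with the actin ratio in the model. It was also lost without gland 1, gland 6, STAT5ca_123 or STAT5ca_177 (adjusted p 0.0505 to 0.0706). Myc did not pass without gland 4 or 6 (adjusted p up to 0.09).

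Milk genes varied widely within each group, and none passed in either tumour type. Of 20 genes of milk proteins and secretory differentiation, 0 passed in each tumour type by limma, and 0 and 0 adjusted over the list alone. Csn2, beta-casein, stood at -0.72 ± 0.75 and 0.16 ± 0.77 (limma adjusted p = 0.512 and 0.904), and Wap, whey acidic protein, at -0.30 ± 2.01 and 0.24 ± 2.06 (adjusted p = 0.930 and 0.950). The deposited signal of Wap ran from 31.1 to 7606 in gland, from 22.4 to 3282 in STAT5ca tumours and from 16.4 to 9116 in STAT5Δ750 tumours. Camera gave adjusted p = 0.211 and 0.849 for the list, and the first became 0.0264 without gland 4. Its raw median went from -0.43 to -2.07 with the actin ratio in the model, and the list was called lower (adjusted p = 0.0396). Without STAT5ca_177 the raw median of the milk list in STAT5ca tumours went from -0.43 to 0.15. In STAT5Δ750 tumours the milk list had a median of -0.17 and fry gave the opposite direction.

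**Figure D3:**
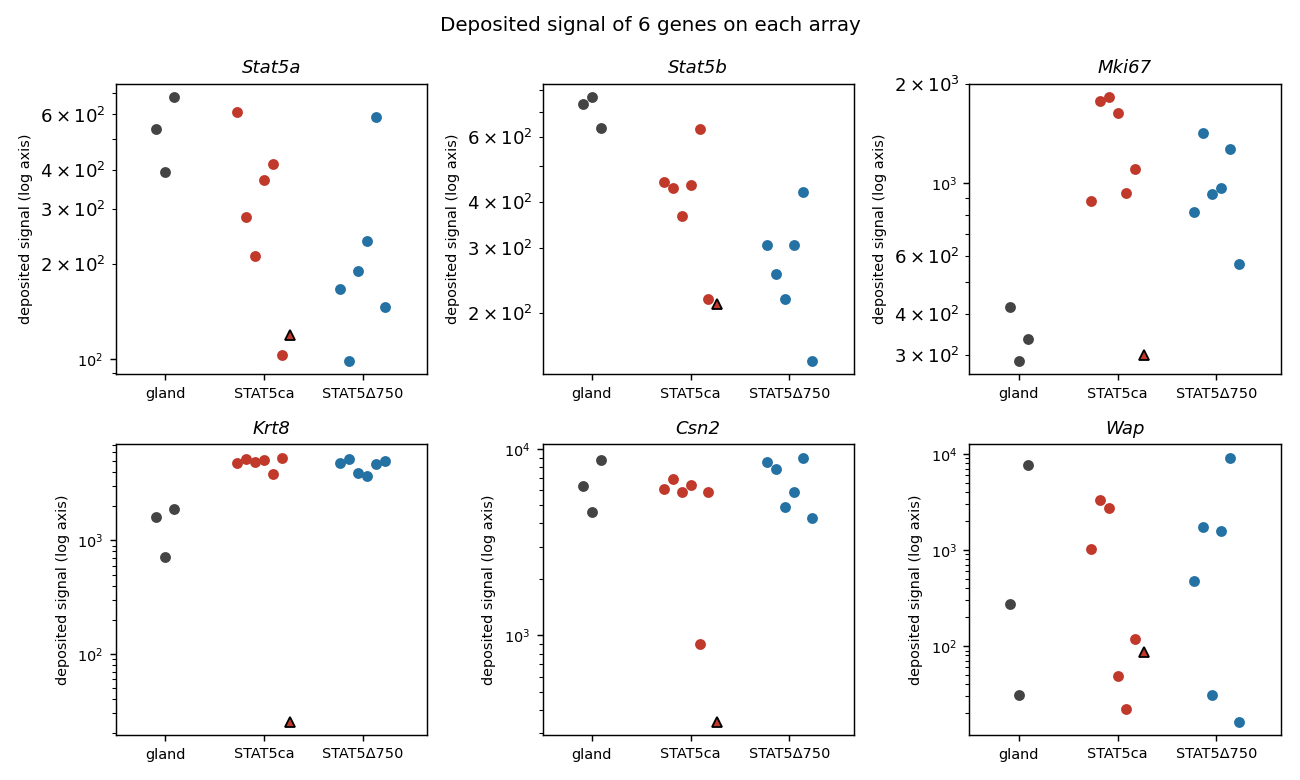
Deposited signal of 6 genes on each array, on a logarithmic axis, 1 point per array by group, with STAT5ca_177 as a triangle. Krt8 lies at 25.3 on STAT5ca_177 and between 3711 and 5376 on the other tumour arrays.

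Fibroblast genes moved in both directions. Of 18 fibroblast and collagen genes, 2 rose and 2 fell in STAT5ca tumours and 1 rose and 1 fell in STAT5Δ750 tumours, and the counts adjusted over the list alone were 3, 2, 1 and 1. Col1a1, a collagen chain, rose by 2.33 ± 0.61 and 2.12 ± 0.63, and Dpt, dermatopontin, stood at -2.88 ± 0.71 and -2.57 ± 0.73. The list was not called, with camera adjusted p = 0.464 and 0.652, and in STAT5ca tumours its median was -0.11 and its mean -0.12, while its raw median, 0.15, was -0.14 under the deposited scaling and -0.02 without STAT5ca_177. Of 15 genes of the list of mesenchymal transition, 2 fell in STAT5ca tumours and 1 rose and 2 fell in STAT5Δ750 tumours, with the same counts adjusted over the list alone, and Zeb1, a repressor of E-cadherin, stood at -2.27 ± 0.39 and -1.94 ± 0.39. The mesenchymal list had camera adjusted p = 0.0585 and 0.454, and the first became 0.0119 to 0.0488 without gland 4, STAT5ca_171 or STAT5ca_177. Of 17 macrophage genes, 1 rose in STAT5ca tumours, Cd14, a receptor for lipopolysaccharide, at 1.80 ± 0.56 and higher on 6 of 7 arrays, and 0 of 17 in STAT5Δ750 tumours by limma, and 0 and 0 adjusted over the list alone. Camera gave adjusted p = 0.781 and 0.494 for macrophages, whose median in STAT5ca tumours was -0.15, while the raw median, 0.10, was -0.19 under the deposited scaling and -0.20 without STAT5ca_177. Of 16 genes of matrix proteases and inhibitors, 2 rose in each, Mmp13 and Timp1, and 2 and 2 adjusted over the list alone, with Timp1, a protease inhibitor, at 2.28 ± 0.67 and 2.45 ± 0.68, and camera gave adjusted p = 0.506 and 0.0739. The second became 0.0141 with the actin ratio in the model and 0.0488 under the deposited scaling. Of 10 genes of Wnt targets and antagonists, 1 fell in STAT5ca tumours, Lef1, a Wnt transcription factor, at -2.44 ± 0.64, and 0 changed in STAT5Δ750 tumours by limma, with the same counts adjusted over the list alone. The Wnt list had camera adjusted p = 0.575 and 0.659, and its median in STAT5ca tumours was 0.26, or 0.52 raw, and its mean -0.05. Calls lost without 1 array were those of Col1a1 (any gland in STAT5Δ750 tumours and gland 4 or 6 in STAT5ca tumours, adjusted p up to 0.102), Dpt (gland 1 or 4 in STAT5Δ750 tumours, 0.0966), Cd14 (gland 1 or 4 or STAT5ca_213, 0.147), Timp1 (any gland in STAT5ca tumours and gland 1 or 4 in STAT5Δ750 tumours, 0.0912) and Lef1 (gland 1, 0.0617).

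Of 20 interferon response genes, 3 rose in STAT5ca tumours and 0 in STAT5Δ750 tumours by limma, and 2 and 0 adjusted over the list alone. Bst2, tetherin, rose by 1.85 ± 0.52 and Oas1a, an antiviral synthetase, by 2.16 ± 0.62 in STAT5ca tumours, and in STAT5Δ750 tumours they stood at 1.51 ± 0.53 and 1.60 ± 0.64. Neither passed without gland 1 or 4, nor Oas1a without gland 6, with adjusted p up to 0.0885 and 0.0794. The interferon list had camera adjusted p = 0.312 and 0.164, and the second became 0.0214 without STAT5Δ750_178. The list was called higher in both with the actin ratio in the model (adjusted p = 0.00480 and 0.0133), with raw medians of 1.40 and 1.28 in place of 1.12 and 0.97. Of 6 MHC class II genes, 0 passed in STAT5ca tumours by limma and 1 fell in STAT5Δ750 tumours, H2-Eb1, a class II chain, at -3.67 ± 1.12, and 0 and 1 adjusted over the list alone. Camera gave adjusted p = 0.0778 and 0.0420 for class II, and the second became adjusted p = 0.684 with an estimated correlation, 0.0836 under the deposited scaling, 0.0752 under quantile normalization and 0.245 with the actin ratio in the model. That call was also lost without gland 1 or 6, STAT5ca_169 or STAT5Δ750_92, STAT5Δ750_174 or STAT5Δ750_178 (adjusted p 0.0507 to 0.0790), while the first list was called without STAT5ca_177 (adjusted p = 0.00780). H2-Eb1 did not pass without gland 1 or 6 or STAT5Δ750_92 or STAT5Δ750_174 (adjusted p up to 0.140). Of 15 apoptosis regulators, 4 rose and 3 fell in STAT5ca tumours and 1 rose and 2 fell in STAT5Δ750 tumours, and the counts adjusted over the list alone were 4, 3, 1 and 3. Bad, which promotes cell death, rose by 1.46 ± 0.20 and 1.17 ± 0.20, and Birc3, an inhibitor of apoptosis, stood at -2.0 ± 0.43 and -2.12 ± 0.45, with camera adjusted p = 0.796 and 0.618 for the list. In STAT5ca tumours the apoptosis list had a median of -0.18 and a mean of -0.02, while its raw median, 0.07, was -0.22 under the deposited scaling. Of 15 immediate early genes, 3 rose in STAT5ca tumours and 4 rose and 1 fell in STAT5Δ750 tumours, and the counts adjusted over the list alone were 4 up and 1 down and 4 up and 1 down. Ier2 rose by 1.38 ± 0.24 and 1.02 ± 0.25, with camera adjusted p = 0.572 and 0.312 for the list.

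The comparison of the tumour types asked whether active and truncated STAT5 give tumours with different expression. No gene could be called: limma gave 0 of 9260 genes, with 764 at an unadjusted p under 0.05 where 463 would be expected by chance, and a smallest adjusted p of 0.512, and a test per gene with a spread of its own for each group also gave 0. Stat5b stood at 0.64 ± 0.28 (log2 change ± SE, 7 STAT5ca against 6 STAT5Δ750 tumours, adjusted p = 0.598), and Stat5a at 0.50 ± 0.43. Second probe sets of Stat5b and Stat5a stood at 0.04 ± 0.32 and -0.13 ± 0.57. Cnn1 stood at -1.01 ± 0.29, Cldn4 at -1.48 ± 0.65, Egfl7 at -0.63 ± 0.26 and Lig1 at 0.57 ± 0.27, and Mki67, Krt8, Csn2 and Wap at 0.31 ± 0.34, -0.78 ± 0.92, -0.88 ± 0.60 and -0.54 ± 1.62. The median half-width of the unadjusted 95% interval of a gene's change was 0.59 on the log2 scale. It is not a limit of detection after adjustment, since larger differences, such as that of Cnn1, were not called either. In simulated data of this comparison, with 200 changed genes per draw, 38.8% of those changed 2-fold and 78.8% of those changed 4-fold were called. Without STAT5ca_177, 0 genes passed and 968 had an unadjusted p under 0.05. Without STAT5ca_169, 1 gene passed, Tceanc2, at 1.14 ± 0.14 (adjusted p = 0.00817), named here after its value was seen.

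By camera, 14 of the 29 lists were lower in STAT5ca than in STAT5Δ750 tumours relative to all genes, whose median was 0.15, and 0 of the 14 were called with an estimated correlation or by fry. The adjusted p values with an estimated correlation ran from 0.248 for the basal list to 0.816 for the mitosis list. The medians relative to all genes were -0.64 for the luminal list (camera adjusted p = 0.000157), -0.64 for the basal list (4.78e-07), -0.46 for milk proteins (0.00319), -0.34 for hormone sensing epithelium (0.00705), -0.70 for squamous epithelium (0.0289) and -0.83 for muscle (0.000165). They were -0.29 for the mesenchymal list (0.00204), -0.34 for fibroblasts (0.00171), -0.51 for granulocytes and mast cells (0.0142), -0.27 for endothelium (0.000492) and -0.15 for mitosis (0.0182). For matrix proteases, Wnt targets and glycolysis they were -0.36 (0.00301), -0.42 (0.00910) and -0.23 (0.0266). By limma, 0 members of these lists passed, and adjusted over the list alone 1 basal gene did. Of the 14 calls, only those of basal cells and endothelium held without every 1 array in turn. The luminal call was lost without STAT5ca_177 (adjusted p = 0.570), as were those of milk proteins, squamous epithelium, mitosis and Wnt targets, the last with adjusted p = 0.0605. Without this array the raw medians turned from -0.49 to 0.17 for luminal epithelium, from -0.31 to 0.10 for milk proteins and from -0.00192 to 0.17 for mitosis, with a median of all genes of 0.14. Others moved further from 0 without it, from -0.68 to -1.26 for muscle, -0.19 to -0.39 for fibroblasts, -0.14 to -0.50 for the mesenchymal list, -0.19 to -0.33 for hormone sensing epithelium and -0.21 to -0.49 for matrix proteases, while squamous epithelium went from -0.55 to -0.37. With the actin ratio in the model the muscle and fibroblast calls were lost and their raw medians turned to 0.13 and 0.01, and the calls of squamous epithelium, the mesenchymal list, matrix proteases and Wnt targets were lost (adjusted p 0.106 to 0.160). With this ratio macrophages were called higher (adjusted p = 0.00335), and DNA replication (0.0239) and cholesterol synthesis (0.000206) lower. The calls of milk proteins, hormone sensing epithelium, squamous epithelium, granulocytes and mast cells and Wnt targets were lost under the deposited scaling (adjusted p 0.0592 to 0.208) and under quantile normalization (0.0568 to 0.221), where unfolded protein genes were called (0.0365). T and NK cells were called without STAT5ca_177 (0.0445). The muscle call was lost without STAT5Δ750_178 (adjusted p = 0.212), and those of hormone sensing epithelium (0.0962) and the mesenchymal list (0.0622) without STAT5Δ750_160. Among lists not called, the raw medians of adipocytes, DNA replication, fatty acid synthesis, cholesterol synthesis, interferon response, oxidative phosphorylation, unfolded protein and ribosomal genes were above 0 and fell below 0 under the deposited scaling, and B cells had a raw median of -0.13 and a mean of 0.07. Camera, which is relative to other genes, and fry gave opposite directions for 11 lists, none of them called.

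The changes against gland were alike in the tumour types. Of the genes that passed, 750 were higher in both and 759 lower in both, against 119 and 90.5 for independent lists of those sizes, and 0 went opposite ways by limma. Among the genes higher in both were Mmp13, Dyrk3, Pbk, Cdk1 and Fdps, and among those lower in both Cd209b, Actn3, Pck1, Kdr and Igf1. Both comparisons use the same 3 glands, which by itself makes them alike: across genes, which are not independent replicates, the changes correlated at 0.942 with a covariance of 1.27. All arrays, glands included, were also simulated without any change between the groups, with 1 spread per gene shared by the groups. These gave 0.683 and 0.188 on average over 50 draws, and 0 genes called in both by limma. The measured glands were not used in the draws. How far the likeness rests on the tissue content of these 3 glands was therefore not tested. The 3 glands were too few to split between the comparisons, and leaving out gland 1, 4 or 6 gave 818, 737 or 966 genes called the same way in both, in place of 1509.

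**Figure D4:**
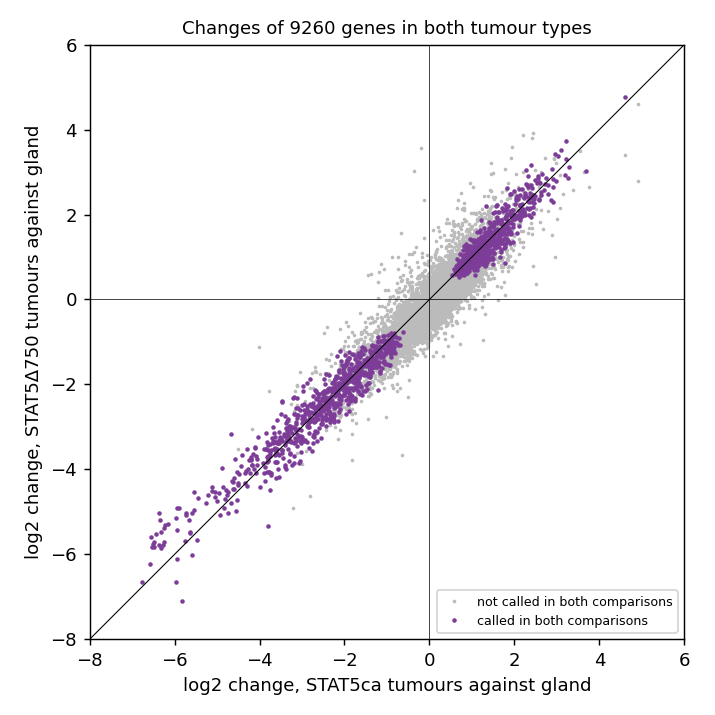
Log2 change of each of 9260 genes in STAT5ca tumours against gland (x axis) and in STAT5Δ750 tumours against gland (y axis), with the genes called in both comparisons in purple and the line of equal change. The 1509 genes called in both lie on the same side of 0 on both axes.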

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

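The tests on STAT5ca_177 and on muscle, fat and lymphocyte genes, and the look at the make-up of the splits, were chosen after the results were seen. The counts of other splits of the arrays were chosen before.

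STAT5ca_177 lay far from the other STAT5ca arrays on many values. On the log2 scale its list means were 5.79 for luminal epithelium (others up to 10.45), 8.75 for mesenchymal transition (others 6.19 to 7.19) and 12.04 for macrophages (others 8.25 to 9.67). It was lowest for Krt8 (5.37), Cldn4 (4.76), Perp (5.42), Gabrp (4.25), Dyrk3 (5.59), Pbk (7.53) and Ube2c (8.25), and highest for Trem2 (11.11), Ckmt2 (8.19) and Ryr1 (10.01). Of 9260 genes, 781 were at least 4-fold higher and 657 at least 4-fold lower on this array than the mean of the other STAT5ca arrays. Among the highest, named after their values were seen, were Marco, at 12.72 against a mean of 4.03, Clec4e, Vsig4 and Clec5a, all genes of myeloid cells. Also named after, Prol1, Klk1 and Pip were high too, at 12.39, 11.1 and 11.81 against means of 5.34, 4.42 and 5.79. The lowest were Cldn3, at 4.25 against a mean of 11.78, Elf5, Cnmd and Sox10.

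Degraded RNA as the cause of the place of STAT5ca_177 is argued against by its actin 3'/5' ratio of 2.19, below the highest of the other tumours, 5.38. A normal gland under a tumour label is argued against by 15 of 18 luminal genes lying below the lowest gland. Few luminal epithelial cells in the sample stay open as a candidate explanation. The count of 16 of the 18 luminal genes with their lowest STAT5ca value on this array restates what set it apart and does not support it. The histology is not given, and a tumour of another cell type or a mixed sample was not tested.

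Lymphoid signal set 2 tumour arrays apart. STAT5ca_124 was highest of its group for the B cell list (8.59), Cd79a (7.95), Ms4a1 (8.08), Cd209b (8.12) and Lep (5.03). STAT5Δ750_254 was highest of its group for the T and NK cell list (6.58), the B cell list (8.35), the granulocyte and mast cell list (8.27), Cd5 (6.48), Cd28 (5.995), Cd2 (7.06), Cd79a (7.75), Ms4a1 (8.20), Cd209b (9.40), Marco (8.40) and Birc3 (9.01). No explanation was tested for these arrays.

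Other single arrays stood apart on fewer values. STAT5ca_123 was highest for Bad (8.59), and STAT5Δ750_165 lowest for luminal epithelium (9.56). STAT5Δ750_178 was highest for fatty acid synthesis (10.18) and Apobec2 (10.15) and lowest for apoptosis regulators (8.002). STAT5Δ750_92 was highest for cholesterol synthesis (8.63) and Lig1 (9.47). In all, 36 of 244 values tested, 29 lists and 93 genes in each tumour group, had an array apart, where about 12.2 would be expected by chance at 1 in 20, and lists and genes that move together are not independent.

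Muscle, fat and lymphocyte genes were lower in both tumour types, a pattern of 4 lists. Scaling of the arrays as its cause is argued against, since the raw median change closest to 0 over 4 scalings was -3.14. With the actin ratio in the model the raw median closest to 0 was -3.31, that of T and NK cells. Every tumour lay above every gland in this ratio, so the value rests on the slope within groups and by itself cannot exclude RNA quality. STAT5Δ750_165 and STAT5Δ750_178 had ratios of 1.27 and 1.33, near the highest gland at 1.25. Their T and NK and B cell list means were at most 4.71 and 5.89, against 7.59 and 8.78 on the lowest glands. The adipocyte mean was at most 7.58 on STAT5Δ750 tumours, against 10.01 on the lowest gland. These values argue against RNA quality, by this ratio, as the cause of the fat and lymphocyte falls. The raw muscle medians moved most with this ratio, from -5.94 to -3.92 in STAT5ca tumours and from -5.11 to -4.13 in STAT5Δ750 tumours, so that a part of RNA quality in the size of the muscle change stays open. A smaller share of muscle, fat and lymphoid tissue in the tumour samples stays open. That at least 81.8% of the tested members fell in each list and comparison restates the pattern, and a loss of these transcripts within the cells, which was not tested, would give the same.

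The difference between the tumour types was tested directly. Camera called 14 lists lower in STAT5ca than in STAT5Δ750 tumours, with raw log2 medians of -0.31 for milk proteins, -0.49 for luminal epithelium, -0.19 for hormone sensing epithelium, -0.49 for basal cells, -0.55 for squamous epithelium, -0.14 for mesenchymal transition, -0.19 for fibroblasts and -0.68 for muscle. The raw medians were -0.36 for granulocytes and mast cells, -0.12 for endothelium, -0.00192 for mitosis, -0.21 for matrix proteases, -0.28 for Wnt targets and -0.0801 for glycolysis. Without STAT5ca_177 the raw medians for milk proteins, luminal epithelium and mitosis turned to 0.10, 0.17 and 0.17, near the 0.14 of all genes. None of the 14 passed with an estimated correlation or by fry.

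Other splits of the same arrays were counted for each comparison. For STAT5ca tumours against gland, 100 of the 120 possible splits were run. Of these 1, the real one, gave as many as 2154 genes, and the highest other gave 956. For STAT5Δ750 tumours against gland it was 1 of 84, the real 1823, and the highest other gave 6. This makes chance unlikely for both, and 1 of 100 and 1 of 84 are the lowest shares that these counts can reach. For STAT5ca against STAT5Δ750 tumours the real count was 0 by limma, with 0 by a Welch test. All 100 of 100 splits reach that count by its construction, so it decides nothing, and the highest other gave 63. By genes at an unadjusted p under 0.05, 18 of 100 splits gave at least the real 764, and chance cannot be excluded. The split with 956 genes kept 2 of the 3 glands together and put STAT5ca_177 with them. The other 16 splits that kept 2 glands together gave 0 genes by limma, and of the 29 that kept none in the group of 3 arrays, 3 gave genes, up to 786. Why these splits gave genes was not tested. The split with 63 genes kept 4 of the 6 STAT5Δ750 tumours together and put STAT5ca_123 and STAT5ca_177 with them. It was picked as the highest of the splits, and whether it reflects a structure of the tumours was not tested.

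Some signals lay outside the main measurement. The lowest actin 3'/5' ratio of a tumour array was 1.27, above the highest gland, 1.25. By this ratio RNA quality and the tumour groups are confounded. The Gapdh 3'/5' ratio overlapped, from 0.841 to 1.03 in gland, 0.791 to 1.71 in STAT5ca and 0.757 to 0.864 in STAT5Δ750 tumours. With the Gapdh ratio in the model 2249 and 1865 genes passed against gland by limma, and with the actin ratio 772 and 1452. Of 1195 probe sets without 1 gene symbol, 276 passed in STAT5ca and 230 in STAT5Δ750 tumours against gland by limma.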

How the results depend on the processing

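The deposited scaling, the actin covariate and the settings that leave out STAT5ca_177 with the deposited scaling, or STAT5ca_124 with STAT5Δ750_254, were chosen after seeing the data, and the other tests before. No paired analysis was possible because no replicate number is shared between the groups.

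The counts of 2154 and 1823 genes stayed within 1.5 times under most settings. With all probe sets they were 3282 and 2878, and with array quality weights 4998 and 4861. With only the 2 groups compared the second was 2826, with the actin covariate the first was 772 and with the deposited scaling and without STAT5ca_177 the second was 2752. Leaving out 1 array gave 1179 to 3039 and 835 to 2439 genes, and 737 to 2092 shared, the lowest without a gland and the highest without STAT5ca_177. Between the tumour types the range was 0 to 1 by limma, and a Welch test gave 2499, 2689 and 0 genes. More probe sets tested explain the first of these counts. For the others the cause was not tested.

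Of 44 calls of lists over the 3 comparisons, all 44 held with centring, the floor and trend and robust, and none was called in the opposite direction. Between the tumour types, calls lost with a raw median of the other sign were those of luminal, milk and mitosis lists without STAT5ca_177 (0.17, 0.10 and 0.17), of luminal and mitosis also without it under the deposited scaling (0.05 and 0.05), and of muscle and fibroblasts with the actin covariate (0.13 and 0.01). Each list below is given with its number of calls under the setting.

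Quantile normalization gave 0 calls for milk, STAT5 targets, MHC class II, Wnt and ribosomal lists, 1 for basal, squamous and granulocyte lists and 2 for hormone sensing and unfolded protein lists. The deposited scaling gave 0 for the same lists as quantile normalization, 1 for basal, squamous and granulocyte lists, 2 for hormone sensing and protease lists and 3 for luminal. With the deposited scaling and without STAT5ca_177, milk, STAT5 targets, Wnt and ribosomal had 0, basal, squamous, hormone sensing and granulocytes 1, mesenchymal, MHC class II, proteases, luminal and mitosis 2. Without STAT5ca_124 and STAT5Δ750_254, STAT5 targets and ribosomal had 0, squamous 1, hormone sensing and granulocytes 2, DNA replication 3.

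With the actin covariate, STAT5 targets, mesenchymal, fibroblast, MHC class II and Wnt had 0, macrophages, proteases, basal and squamous 1, interferon, milk, cholesterol, muscle and granulocytes 2, DNA replication 3. With the Gapdh covariate, fibroblast, protease, Wnt, squamous and glycolysis had 0, macrophages 1, muscle 2, B cells, DNA replication and cholesterol 3. With array quality weights, milk, STAT5 targets and Wnt had 0, squamous 1, mesenchymal, MHC class II, unfolded protein, ribosomal, luminal, hormone sensing and mitosis 2.

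With all probe sets, milk, STAT5 targets, mesenchymal, MHC class II, unfolded protein and ribosomal had 2, luminal and oxidative phosphorylation 3. With the 60th percentile filter, STAT5 targets, Wnt, unfolded protein and ribosomal had 0, basal, squamous, glycolysis, hormone sensing and granulocytes 1. Without a filter, proteases, unfolded protein, ribosomal and hormone sensing had 2 and glycolysis 1. With the mean of a gene's probe sets, squamous had 0, STAT5 targets 1 and ribosomal 2. With the offset at the 40th percentile, MHC class II had 0, squamous 1, ribosomal 2, and with an offset of 1, mesenchymal 2. With only the 2 groups compared, ribosomal had 0, squamous 1, mesenchymal and granulocytes 2.

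Camera with an estimated correlation gave 0 calls for each of the 24 lists called. Fry gave 0 for milk, mesenchymal, fibroblast, MHC class II, protease, Wnt, unfolded protein, ribosomal, luminal, basal, squamous, glycolysis, oxidative phosphorylation and granulocytes, and 2 for STAT5 targets, hormone sensing, muscle, endothelium and mitosis.

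Leaving out 1 array gave 0 to 1 calls for STAT5 targets, fibroblasts, macrophages, fatty acid synthesis, proteases and Wnt, 0 to 2 for milk, squamous, mesenchymal, interferon, MHC class II, glycolysis, unfolded protein and ribosomal, and 1 to 3 for oxidative phosphorylation. It gave 2 to 3 for luminal, hormone sensing, adipocytes, muscle, T cells, B cells, granulocytes, mitosis, DNA replication and cholesterol. Basal (2), endothelium (3), apoptosis regulators (0) and immediate early genes (0) did not move. For these changes the cause was not tested.

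Of named genes past the threshold, 41 of 71 in STAT5ca and 44 of 62 in STAT5Δ750 tumours were called under every alternative run on single genes. Those did not include all probe sets, the fold change of at least 2 or the Welch test. Signals near the 7.9 offset limit the size of falls.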

Other observations

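The tests of scaling and RNA quality for the milk and interferon lists were set before their results were seen, and the test on the STAT5 target list after.

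Milk genes and interferon genes moved in opposite ways across tumours. Over the 12 tumours other than STAT5ca_177, the means of the milk list, which holds Csn2 and Wap, and of the interferon list, which holds Bst2 and Oas1a, had a Pearson r of -0.851 (permutation p = 0.00043, adjusted 0.0120) and a Spearman rho of -0.818 (permutation p = 0.00208, adjusted 0.0419). It was 1 of 28 relations computed, of the milk list with each other list. Without the 2 tumours farthest from the median of the milk list r was -0.789, and with STAT5ca_177 it was -0.572. Within 6 STAT5ca tumours r was -0.823 (exact p = 0.0278) and within 6 STAT5Δ750 tumours -0.932 (exact p = 0.0139).

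Scaling as the cause of this relation is argued against by an r of -0.851 at its closest to 0 over 4 scalings, and RNA quality by a partial r of -0.897 given the actin ratio. Active STAT5 opposing the interferon response may explain it. The STAT5 target list had an r of -0.0687 with the interferon list, with an interval of -0.618 to 0.526, too wide to decide. The genes of the target list also hardly moved together, with an estimated correlation of 0.0304. Its mean is thus a poor measure of STAT5 activity, and this r cannot decide the question. A differing share of secretory cells was not tested.

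The milk list also went with the fatty acid list, which holds Scd2 and Elovl6 (r = 0.810, permutation p = 0.00241, adjusted 0.0231; rho = 0.783, permutation p = 0.00386, adjusted 0.0419). Without the 2 farthest tumours r was 0.941, and with STAT5ca_177 0.857. Its r with ribosomal proteins was 0.772 (permutation p = 0.00411, adjusted 0.0288; rho = 0.776, permutation p = 0.00449, adjusted 0.0419; without the 2 farthest 0.782), and with STAT5ca_177 it was 0.487. With oxidative phosphorylation r was 0.798 (permutation p = 0.00248, adjusted 0.0231), while its rho of 0.741 did not pass (permutation p = 0.00754, adjusted 0.0528), and r without the 2 farthest was 0.886 and with STAT5ca_177 0.576.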
